A study of Mus musculus with 24 samples.

How the data were processed

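The data are 24 microarrays of total RNA from mouse brain: cerebral cortex, hippocampus and cerebellum of 4 wild-type (WT) animals and 4 animals with a liver-specific knockout (KO) of glutamine synthetase. Per the labels, RNA was isolated with a lipid tissue kit including digestion of DNA on the column. The labels name biotin as the label and also describe Cy3-labelled cRNA and single-stranded cDNA, which are different chemistries, so the labelling is not settled by the sources used here. Strain, age and sex of the animals are not given in the sources used here.

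The deposited values are on a log2 scale, 1 value per transcript cluster and array, and the authors made them with RMA, a method that corrects background, normalizes between arrays and summarizes the probes of a gene. The version and settings of RMA, the log base and the genome build are not given in the sources used here. The log2 scale was read from the values themselves, which ran from 3.89 to 19.14 with array medians from 8.719 to 8.816. In 291 of the 22206 rows at least 1 array exceeded 16, the ceiling of a 16-bit scanner reading on a log2 scale, and how such values arose is not given in the sources used here. A fold below means 2 to the power of the difference of deposited values, and whether it equals the fold of RNA was not tested. RMA shrinks differences among dim probes, and values near the lower end of the range carry little signal over background. No scanner files were used, so detection above background could not be judged per array.

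Of the 22206 rows, 19572 carried a gene in the platform annotation (19505 symbols) and were tested; 2634 rows without a gene were left out, and no row was removed for dim signal. The row of a knocked-out gene itself was not analysed here, and deletion of the target cannot be checked in brain tissue when the knockout is specific to liver. Values were used as deposited, with no further normalization. The samples fell into 6 groups (3 regions by 2 genotypes) of 4 arrays. Numbers in the labels run from 1 to 4 within each genotype and repeat across regions. They were taken as animals within a genotype, while WT 1 and KO 1 are different animals and were not paired.

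Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided moderated statistics) on all 24 arrays with 1 mean per group, which left 18 residual degrees of freedom and a prior of 6.9. The comparisons were KO against WT in each region, KO against WT averaged over the regions, the difference of the KO effect between regions (an F statistic over 2 contrasts), and the 3 pairs of regions in WT. Of these comparisons, those that join regions kept the animal as a random block (duplicateCorrelation with statmod 1.5.0), whose consensus correlation was 0.00646. Set tests of the difference between regions had no such block. P-values were adjusted by the Benjamini-Hochberg method over all rows of a comparison, with a threshold of 0.05; counts for regions also required a 2-fold difference. Errors given with log2 differences are standard errors of the fit with n = 4 arrays per group, and those given with group means are standard deviations. An exact permutation of 4 against 4 values cannot give a 2-sided p below 0.029.

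Before the data were examined, 44 gene lists (pathways, cell types and brain regions) were written down; 42 had at least 5 measured members and were tested in each region with camera, the competitive set test of limma, at a preset correlation of 0.01 between genes, with adjustment over all 126 tests. Each list was tested again with the correlation estimated from the arrays, and with fry. Members of each list were also adjusted over the list alone. The genes named in the text follow a rule written at the same time: the 10 genes of smallest p where fewer than 6 pass, the 4 members of smallest p of each list that passed, 14 genes named in advance (Gfap, Aqp4, Slc1a2, Slc1a3, Hmox1, Cdkn1a, Gadd45a, Mt1, Mt2, Tspo, Fos, Arc, Per1 and Dbp), and for regions the 3 most different genes each way and 3 members of each region's marker list; unnamed transcripts and receptor families were left out beyond the first 3. Genes named outside this rule, such as Th, Cdhr1, Eomes, Scgn, Prl and Pomc, were chosen after the data were seen.

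The procedure was tested on simulated data with the spread of these arrays, 200 changed genes in each of 5 simulations. In the cortex 37.9% of changes of 0.5 log2, 93.4% of changes of 1 and 99.7% of changes of 2 were recovered. Recovery was 39.7%, 94.9% and 99.4% in the hippocampus and 40.6%, 92.2% and 99.7% in the cerebellum. False calls made up 5.88%, 5.46% and 4.44% of the calls in the 3 regions. A shift of 0.5 placed on 1 list of 19 genes in the hippocampus was called with 0 other lists. Genes were simulated without correlation between them, so that run cannot show how often lists of correlated genes pass falsely. Simulated animals with a correlation of 0.3 were fitted with an estimate of 0.278.

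Alternatives tried were quantile normalization, centring on the array median, removal of rows under the 30th percentile of mean signal, inclusion of rows without a gene, a trended robust prior, array weights, a fit of each region alone with its 8 arrays, the number as a block, an ordinary 2-sample test of each gene at unadjusted p under 0.05 and 1.5-fold, animal means in place of arrays, and leaving out each array in turn. Chosen after the data were seen were leaving out cortex KO 1 and KO 4 together, leaving out cerebellum KO 3 from the lists and named genes, leaving out each KO animal (KO 4 also from animal means), the number as a fixed block over all arrays, set tests of the difference between regions (also without cortex KO 1 and KO 4), estimated correlations for lists without those arrays or without KO 3, a count of genes near the targeted locus at unadjusted p, the shift in the cerebellum of genes at least 2-fold higher in WT cortex or in cerebellum (chosen by the mean of the cerebellum arrays of both genotypes), and lists of olfactory bulb, brainstem and neutrophil markers.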

Results

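Messenger RNA was measured on 24 arrays of cerebral cortex, hippocampus and cerebellum from 4 WT mice and 4 mice lacking glutamine synthetase in the liver, an enzyme that clears ammonia from the blood by binding it to glutamate. The series asks how raised ammonia alters transcripts in the brain. Each region and genotype was represented by 4 arrays, 1 per animal. Correlations between arrays of a group lay between 0.981 and 0.9959, and those between regions from 0.942 to 0.992. The residual standard deviation of an array was 0.152 to 0.266 on the log2 scale in 23 of the 24 arrays and 0.357 in KO 3 of the cerebellum. Their number limits the precision of all the values below.

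The WT regions were compared to see how the 3 tissues differ and whether each array carries the genes of its region. In the cerebellum, granule and Purkinje cell genes were far above both other regions: Gabra6, a GABA receptor subunit of granule cells, was higher than in cortex by 11.28 (SE 0.26, n = 4 per group, adjusted p = 1.32e-20), Cbln3 by 8.95 and Car8 by 8.05. Against the hippocampus the same genes were higher by 11.39, 9.09 and 8.77. The genes furthest below cortex in the cerebellum were Tbr1, a transcription factor of cortical projection neurons, which differed by -7.09 (SE 0.24), Pde1a by -6.74 and Vxn by -6.60. Among the neocortical markers Lamp5 differed by -5.93 and Fezf2 by -4.75, and among the hippocampal markers Neurod6 by -3.87, Hs3st4 by -2.56 and Prox1 by 2.40. Against the hippocampus, cerebellum differed by -7.39 for Gabra5, -6.86 for Lmo3 and -6.83 for Ddn, and the marker lists gave -5.46 for Tbr1, -4.73 for Fezf2, -3.56 for Lamp5, -5.43 for Neurod6, -2.91 for Spink8 and -2.78 for Hs3st4.

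Hippocampus and cortex of WT animals were closer to each other. Cabp7, a calcium-binding protein, was higher in hippocampus by 3.29 (SE 0.31, n = 4, adjusted p = 1.99e-07), Shisa6 by 3.25 and Tgfb2 by 3.14, while Kcnh5 differed by -2.50, Lamp5 by -2.37 and Dkkl1 by -2.33. The dentate gyrus factor Prox1 was higher by 2.68, Spink8 by 2.39 and Dsp by 2.09, and the cortical layer genes Cux2 and Mef2c differed by -1.78 and -1.75. Of the cerebellar markers, Gdf10 was higher in hippocampus by 1.14 and Il16 by 0.95, and Zic1 differed by 1.30 with an adjusted p of 0.0983. At least 2-fold and past the threshold were 267 genes between hippocampus and cortex (146 higher, 121 lower), 1953 between cerebellum and cortex (883 and 1070) and 1924 between cerebellum and hippocampus (779 and 1145).

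KO against WT in the cortex asks which transcripts accompany the loss of the liver enzyme there. The smallest p belonged to Prss23, a serine protease, which averaged 10.27 ± 0.78 in KO and 8.98 ± 0.25 in WT (SD, n = 4 each), a difference of 1.29 (SE 0.24). Next came Tax1bp1 (0.48), Postn, which encodes the matrix protein periostin (0.73), Dgat2l6 (0.61), Lyar (0.43), Egln3, a prolyl hydroxylase of the hypoxia pathway (1.10), Prkca (0.95) and Tars (0.48) with higher values in KO, and the potassium channel gene Kcnc4 (-0.65) and Rpe65 (-0.49) with lower ones. For 8 of these 10 genes all 4 KO values lay on 1 side of all 4 WT values, and for Egln3 and Prkca 3 did. The genes were chosen for small p, which favours such separation. None of them passed: limma called 0 of 19572 genes, the smallest adjusted p being 0.366 for all 10. At unadjusted p under 0.05 there were 1459 genes (806 higher and 653 lower in KO), where chance gives 979. That fit shares 1 spread per gene over the 3 regions. With the 8 cortex arrays alone limma gave 1205, and the ordinary test without a fold minimum gave 1153. The ordinary 2-sample test with a 1.5-fold minimum gave 29 genes (20 higher, 9 lower) and 0 after adjustment.

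Arrays KO 1 and KO 4 of the cortex stood apart in markers of the olfactory bulb, the forebrain structure next to the cortex. Their mean over 16 such genes was 11.52 and 11.05, against 8.83 to 9.25 in the other 6 cortex arrays. Without the KO 2 array limma called 55 genes (54 higher in KO) and without KO 3 it called 34 (32 higher), among them Th, Cdhr1, Eomes and Scgn in both cases. In 53 of the 55 and 32 of the 34, KO 1 and KO 4 were the highest pair of the 7 arrays left. Without KO 1 and KO 4 together, 0 genes passed in limma (smallest adjusted p 0.999), with 693 at unadjusted p under 0.05. Prss23 then differed by 0.63, Egln3 by 0.36, Prkca by 0.34, Dgat2l6 by 0.27 and Kcnc4 by -0.37, while Tax1bp1 (0.44), Tars (0.38), Lyar (0.31), Postn (0.50) and Rpe65 (-0.48) moved less.

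**Figure D1:**
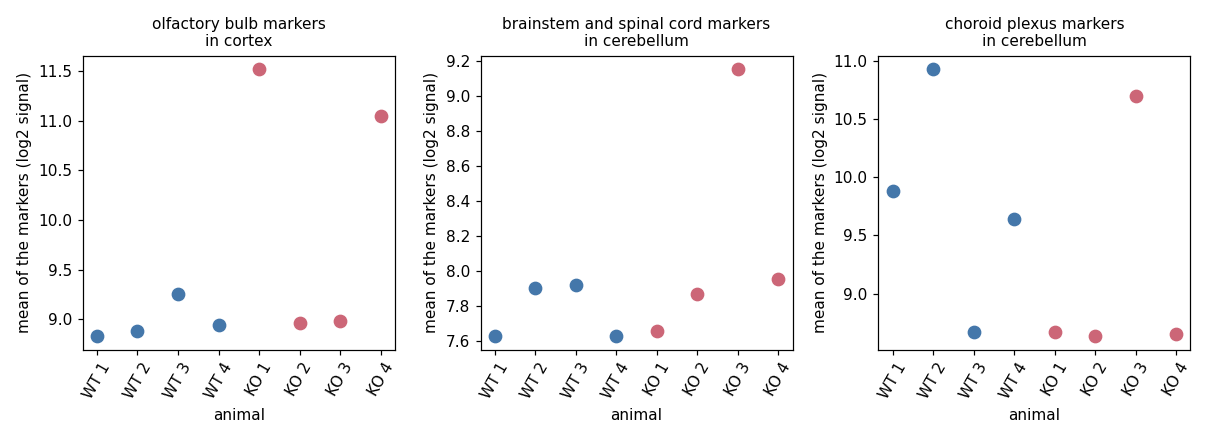
Mean log2 signal of 16 olfactory bulb markers in the 8 cortex arrays, and of 21 brainstem and spinal cord markers and 15 choroid plexus markers in the 8 cerebellum arrays, by animal; each point is 1 array, blue for WT and red for KO. Olfactory bulb markers reach 11.52 in KO 1 and 11.05 in KO 4 of the cortex, brainstem markers reach 9.16 in KO 3 of the cerebellum, and choroid plexus markers range from 8.63 to 10.93 in the cerebellum.

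Of the lists fixed before the data were examined, 5 of 42 passed in the cortex at the preset correlation, 3 without any 1 of cortex WT 1, KO 1 or KO 2, hippocampus WT 2 or KO 3, or cerebellum WT 2 or KO 3, and 2 other lists without cortex KO 1 and KO 4. Other splits of the same arrays gave a median of 5 lists in the cortex, 5 in the hippocampus and 10 in the cerebellum. Some of those splits keep 3 KO arrays together. Inhibitory interneuron markers rose as a list (adjusted p = 0.00549), with 11 of 17 members higher in KO, 0 past the threshold over all genes and 6 adjusted over the list alone. The adjusted p was 0.782 with an estimated correlation. Calb2, which encodes calretinin, differed by 2.35 (SE 0.81), the transcription factor genes Dlx2 and Dlx5 by 1.60 and 1.10, and Gad1, a GABA-producing decarboxylase, by 0.90. In each of the 4 genes 2 KO arrays exceeded all WT arrays. Without KO 1 and KO 4 the differences of the 4 were 0.00, -0.03, 0.01 and -0.06. Excitatory neuron markers fell as a list (adjusted p = 0.0091), with 11 of 12 lower, 0 past over all genes and 0 adjusted over the list alone, and 0.782 as adjusted p with an estimated correlation. Emx1 differed by -0.38, Cux2 by -0.38, Rorb by -0.43 and Fezf2 by -0.43. Without these 2 arrays they differed by -0.36, -0.28, -0.17 and 0.30. Both shifts moved with the olfactory bulb markers: without KO 1 and KO 4 the median of the interneuron list went from 0.30 to -0.05 (adjusted p = 0.894) and that of the excitatory list from -0.33 to -0.02 (adjusted p = 0.952, camera's direction then upward).

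Glutamine and glutamate metabolism, the pathway of the knocked-out enzyme, rose as a list in the cortex (adjusted p = 0.0125), with 13 of 17 members higher; the adjusted p was 0.782 with an estimated correlation. Its leading members were Gad1 (0.90) and Gad2 (0.66), which make GABA from glutamate, and Gfpt2 (0.63) and Gfpt1 (0.21), which use glutamine to make hexosamines. Chaperones of the endoplasmic reticulum rose (adjusted p = 0.0449, and 0.975 as adjusted p with an estimated correlation), with 15 of 16 higher by small amounts: Calr by 0.22, Pdia3 by 0.23, Dnajb9 by 0.23 and Creld2 by 0.22. The core circadian clock list fell (adjusted p = 0.0449, and 0.975 as adjusted p with an estimated correlation), with 17 of 19 lower: Tef differed by -0.40, Rorb by -0.43, Cry2 by -0.16 and Hlf by -0.28. For each of these 3 lists 0 members passed over all genes and 0 adjusted over the list alone. Without KO 1 and KO 4 the medians were 0.02 (adjusted p = 0.838) for the glutamine list, 0.11 (0.082) for the chaperones and -0.03 (0.64) for the clock. Gad1, Gad2, Gfpt2 and Gfpt1 then differed by -0.06, 0.06, 0.14 and 0.09. The differences of Calr, Pdia3, Dnajb9 and Creld2 were 0.12, 0.14, 0.24 and 0.06, and those of Tef, Rorb, Cry2 and Hlf -0.32, -0.17, -0.21 and -0.12. Of the genes named in advance, Cdkn1a had the largest difference in the cortex, 0.76 (SE 0.31, adjusted p = 0.602), and the astrocyte genes Gfap (-0.08), Aqp4 (-0.08), Slc1a2 (-0.26) and Slc1a3 (0.20) gave adjusted p from 0.748 to 0.973. Hmox1 (0.10), Gadd45a (-0.27), Mt1 (-0.07), Mt2 (-0.14), Tspo (-0.08), Fos (-0.03), Arc (-0.41), Per1 (-0.11) and Dbp (-0.14) did not pass either. Without KO 1 and KO 4, Cdkn1a differed by 0.26, less than Aqp4 at -0.31. Gfap and Tspo were then both at -0.24, Slc1a2 at -0.09, Slc1a3 at 0.06, Mt2 at 0.01, Fos at 0.07, Arc at -0.12, Per1 at 0.08 and Dbp at -0.02.

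KO against WT in the hippocampus gave the smallest differences of the 3 regions. Prodh, the mitochondrial enzyme that degrades proline, averaged 10.22 ± 0.12 in KO and 9.87 ± 0.12 in WT (SD, n = 4 each), and the organic anion transporter Slco1a6 differed by 0.46, Mustn1 by 0.39, Eme1 by 0.40, Tmem269 by 0.43, Cenpk by 0.35 and the predicted gene Gm9881 by 0.48. Lower in KO were Acoxl (-0.42), the amino acid transporter Slc36a2 (-0.33) and Cypt12 (-0.39). In all 10 genes the KO and WT values did not overlap. The genes were chosen for small p, and such separation has a chance of 0.029 for any 1 gene. In limma 0 of 19572 genes passed (smallest adjusted p 0.817), and 412 had an unadjusted p under 0.05 (235 higher, 177 lower) against 979 by chance. With the 8 hippocampus arrays alone limma gave 567 at that p, and the ordinary test without a fold minimum gave 727. The ordinary test with 1.5-fold gave 0. In the simulations 94.9% of changes of 1 log2 were recovered in this region. Those simulations held 200 changed genes with the same spread in every animal. Recovery of a few changed genes, for which the adjustment is stricter, was not tested.

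Among the lists, neuron markers fell in the hippocampus (adjusted p = 0.0303, and 0.975 as adjusted p with an estimated correlation). Of 16 members 15 were lower, 0 past over all genes and 0 adjusted over the list alone: Eno2 by -0.16, Snap25 by -0.18, Tubb3 by -0.14 and Syt1 by -0.09. The p53 and senescence list fell as well (adjusted p = 0.036, and 0.782 as adjusted p with an estimated correlation), with 16 of 19 lower, 0 past over all genes and 0 adjusted over the list alone, where Eda2r differed by -0.24, Gadd45b by -0.24, Gadd45g by -0.26 and Cdkn2b by -0.15. Choroid plexus markers varied between hippocampus arrays of both genotypes, from 8.67 to 11.51. The number of lists was 0 without hippocampus WT 2 or KO 3, 1 without hippocampus WT 1, hippocampus KO 2 or cerebellum KO 3, and 4 without hippocampus KO 1 or KO 4. The genes named in advance differed by -0.35 (Aqp4, adjusted p = 1) to 0.27 (Cdkn1a), with Gfap at -0.12, Slc1a2 at -0.05, Slc1a3 at -0.04, Hmox1 at -0.02, Gadd45a at -0.08, Mt1 at 0.07, Mt2 at 0.18, Tspo at -0.21, Fos at -0.12, Arc at 0.18, Per1 at -0.14 and Dbp at -0.04, none past the threshold.

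KO against WT in the cerebellum gave larger differences with wider spread. The voltage-gated channel genes Scn3b and Kcnc2 were higher in KO by 1.85 (SE 0.44) and 1.82 (SE 0.42), followed by Pak3 (1.14), Vstm2a (1.13), the cadherin gene Cdh9 (1.11), Lix1 (0.78) and Fam169a (0.77), and lower values were seen for Rufy4 (-0.52), BC049762 (-0.48) and Erich6b (-0.50). All 10 had an adjusted p of 0.435, and limma called 0 of 19572 genes. At unadjusted p under 0.05 there were 1860 (1169 higher, 691 lower, 979 by chance) in the fit that shares 1 spread over the regions. With the 8 cerebellum arrays alone limma gave 1173, and the ordinary test without a fold minimum gave 943. The ordinary test with 1.5-fold gave 23 (21 higher, 2 lower) and 0 after adjustment. The KO 3 array stood apart: its mean over 21 brainstem and spinal cord markers was 9.16 against 7.62 to 7.95 in the other 7, and its mean over cerebellar granule and Purkinje markers was 12.03 against 13.07 to 13.44. Without it limma called 0 genes (smallest adjusted p 0.999), 688 had an unadjusted p under 0.05, and the differences were 1.26 for Scn3b, 1.30 for Kcnc2, 0.73 for Pak3, 0.73 for Vstm2a, 0.78 for Cdh9, 0.59 for Lix1, 0.54 for Fam169a, -0.53 for Rufy4, -0.45 for BC049762 and -0.46 for Erich6b.

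The marker lists of other regions did not pass in the cerebellum over its 8 arrays. Thalamic and midbrain markers had 11 of 16 members higher (adjusted p = 0.114), striatal markers 9 of 15 (0.434), neocortical markers 13 of 21 (0.546) and hippocampal markers 11 of 20 (0.863). KO 3 was nevertheless the highest of the 8 arrays for 9 of the 16 thalamic and midbrain, 7 of the 15 striatal, 11 of the 21 neocortical and 8 of the 20 hippocampal markers (chance 12.5% each), and its thalamic and midbrain mean was 10.64 against 9.53 to 10.04 in the other 7. Scn3b, Kcnc2, Vstm2a, Pak3, Cdh9, Lix1 and Fam169a all had higher means in WT cortex than in WT cerebellum (13.01 against 7.88 for Scn3b). Of 977 genes at least 2-fold higher in WT cortex than in the mean of the 8 cerebellum arrays, 760 were higher in the KO cerebellum (median 0.22). A median as far from 0 came from 8 of the 70 ways to set 4 of the 8 arrays against the other 4. Without KO 3 it was 741 of 1025 (median 0.11), and 7 of the 35 ways to set 3 of the 7 arrays against the other 4 gave a median as far from 0. Of the genes at least 2-fold higher in cerebellum, 227 of 860 were higher in KO (median -0.16), and 467 of 909 without KO 3 (median 0.00). Medians as far from 0 came from 34 of the 70 ways over all arrays and from 35 of the 35 without KO 3.

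In the cerebellum 14 of the 42 lists passed, 12 upward and 2 downward, and 6 passed without KO 3, 5 of them among the 14, all at the preset correlation. Genes of the mitochondrial respiratory chain had the smallest p and rose as a list (adjusted p = 4.00e-09, and 0.782 as adjusted p with an estimated correlation), with 30 of 31 higher and a median of 0.24: Cox5a differed by 0.38, Uqcrc1 by 0.33, Cox6c by 0.30 and Atp5o by 0.33. Without KO 3 these differences were 0.22, 0.20, 0.20 and 0.20. Heat shock proteins rose as a list (adjusted p = 5.23e-04; 0.782 as adjusted p with an estimated correlation) with 12 of 12 members higher, Hspd1 at 0.31, Hsp90aa1 at 0.39, Hsph1 at 0.50 and Hspe1 at 0.26 (0.22, 0.27, 0.33 and 0.21 without KO 3). Endoplasmic reticulum chaperones rose as a list with 15 of 16 higher (adjusted p = 0.00549; 0.975 as adjusted p with an estimated correlation), Pdia3 at 0.35, Canx at 0.34, Dnajb9 at 0.32 and Hsp90b1 at 0.28 (0.29, 0.27, 0.21 and 0.29 without KO 3). Neuron markers rose as a list with 14 of 16 higher (adjusted p = 3.49e-04; 0.782 as adjusted p with an estimated correlation): Uchl1 differed by 1.04 and the neurofilament genes Nefl, Nefh and Nefm by 0.80, 0.69 and 0.81. These 4 fell to 0.47, 0.32, 0.28 and 0.30 without KO 3. Without KO 3, the array rich in brainstem markers, these 4 lists passed at the preset correlation with medians of 0.13, 0.22, 0.20 and 0.13, and had an adjusted p of 0.986 each with an estimated correlation. In these 4 lists 0 members passed over all genes and 0 adjusted over the list alone.

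Of the 14 lists 9 passed in the cerebellum with KO 3 and not without it. Oligodendrocyte and myelin markers rose as a list with 18 of 18 members higher (median 0.50, adjusted p = 5.39e-05; 0.975 as adjusted p with an estimated correlation; 0.61 without KO 3), with Ugt8a at 0.73, Mobp at 0.62, Hapln2 at 0.55 and Nkx6-2 at 0.48. The same genes were at 0.26, 0.25, 0.17 and 0.15 without KO 3. Microglia markers rose as a list with 18 of 19 higher (adjusted p = 4.94e-06; 0.782 as adjusted p with an estimated correlation; 0.0763 without KO 3), 3 of them past the threshold adjusted over the list alone and 0 over all genes: C1qb differed by 0.66 (SE 0.19), Laptm5 by 0.54, Itgam by 0.44 and Ctss by 0.40. Without that array they differed by 0.42, 0.26, 0.26 and 0.16. Cholesterol synthesis genes rose as a list with 16 of 17 higher (adjusted p = 2.41e-04; 0.782 as adjusted p with an estimated correlation; 0.409 without KO 3), with Msmo1 at 0.64, Hmgcs1 at 0.55, Sqle at 0.55 and Nsdhl at 0.44. Their values without KO 3 were 0.28, 0.19, 0.21 and 0.13. Astrocyte markers rose as a list with 18 of 20 higher (adjusted p = 6.40e-04; 0.782 as adjusted p with an estimated correlation; 0.124 without KO 3), with Gfap at 0.66, Gjb6 at 0.39, the glutamate transporter gene Slc1a2 at 0.36 and Ppp1r3c at 0.32. These genes differed by 0.21, 0.31, 0.18 and 0.09 without KO 3. In the oligodendrocyte, cholesterol and astrocyte lists 0 members passed over all genes and 0 adjusted over the list alone.

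The antioxidant and Nrf2 list rose with 18 of 24 members higher in the cerebellum (adjusted p = 4.08e-04; 0.782 as adjusted p with an estimated correlation; 0.296 without KO 3), with Srxn1 at 0.41, Gsta4 at 0.46, Prdx1 at 0.38 and Txn1 at 0.28. Without KO 3 the differences were 0.30, 0.19, 0.18 and 0.17. The hypoxia and glycolysis list rose with 16 of 19 higher (adjusted p = 0.00549; 0.782 as adjusted p with an estimated correlation; 0.0761 without KO 3): the glycolytic genes Pfkfb3, Aldoa and Pgam1 differed by 0.56, 0.26 and 0.21 (0.26, 0.24 and 0.15 without KO 3), while the carbonic anhydrase gene Car9 differed by -0.54 (-0.37 without KO 3) and alone passed when adjusted over the list alone. The glucocorticoid list rose with 16 of 22 higher (adjusted p = 0.00601; 0.782 as adjusted p with an estimated correlation; 0.305 without KO 3), with Lcn2 at 3.82 (SE 1.18), Fkbp5 at 0.73, Sult1a1 at 0.35 and Hif3a at 0.31. These became 3.03, 0.36, 0.25 and 0.28 without KO 3. Oligodendrocyte precursor markers rose as a list with 9 of 11 higher (adjusted p = 0.0449; 0.782 as adjusted p with an estimated correlation; 0.692 without KO 3), with Sox10 at 0.57, Olig1 at 0.51, C1ql1 at 0.42 and Gpr17 at 0.30. Without that array the 4 genes were at 0.21, 0.06, 0.00 and 0.12. Apart from Car9, 0 members of these 4 lists passed over all genes or adjusted over the list alone.

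Granule and Purkinje markers fell as a list with 23 of 24 members lower in the KO cerebellum (median -0.34, adjusted p = 4.61e-05; 0.782 as adjusted p with an estimated correlation), with Fat2 at -0.65, Slc1a6 at -0.59, Cbln3 at -0.54 and Cdh15 at -0.43. Without KO 3 these were -0.22, -0.16, -0.15 and -0.22 and the median was -0.01 (adjusted p = 0.599). Choroid plexus markers, genes of the tissue that secretes cerebrospinal fluid, fell as a list with 14 of 15 lower (adjusted p = 0.0324; 0.975 as adjusted p with an estimated correlation), with Ttr at -2.98 (SE 1.69), Kl at -1.38, Sostdc1 at -0.61 and Aqp1 at -0.49. Without KO 3 Ttr differed by -4.90, Kl by -2.42 and Aqp1 by -0.65, and the median went from -0.42 to -0.83 (adjusted p = 4.29e-10 at the preset correlation; 0.986 as adjusted p with an estimated correlation). Ttr was 16.51, 17.09, 9.65 and 15.89 in WT 1 to 4 and 10.17, 9.66, 17.56 and 9.82 in KO 1 to 4. In both lists 0 members passed over all genes and 0 adjusted over the list alone. GABA receptor subunits had an adjusted p of 0.075 in all arrays and 0.782 with an estimated correlation. In all arrays 7 of 12 members were higher (median 0.13, mean 0.40), with 0 past over all genes and 3 adjusted over the list alone. Without KO 3 the list passed at the preset correlation (0.00884, median 0.12), with 0.986 as adjusted p with an estimated correlation. The subunit gene Gabra2 was 10.86 in the cerebellum of WT 4 and 12.61 to 13.19 in that of the other animals. Of the genes named in advance, Mt1 (0.32) and Mt2 (0.34) had adjusted p of 0.517 and 0.559, and Aqp4 (-0.01), Slc1a3 (-0.29), Hmox1 (-0.07), Cdkn1a (0.30), Gadd45a (-0.14), Tspo (0.11), Fos (0.04), Arc (-0.19), Per1 (-0.10) and Dbp (0.07) did not pass. Leaving out KO 3 moved Slc1a3 and Fos to 0.00, Cdkn1a to 0.12, Hmox1 to -0.19, Aqp4 and Per1 to -0.04 and Dbp to 0.02.

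**Figure D2:**
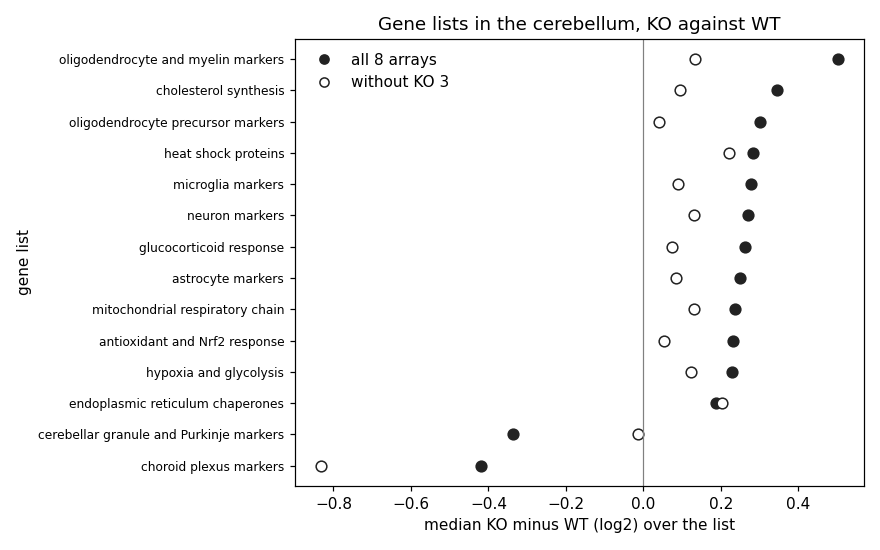
Median log2 difference of KO minus WT over the members of each list that passed in the cerebellum; filled points use all 8 arrays and open points leave out KO 3. The oligodendrocyte and myelin list has the highest median (0.50, and 0.13 without KO 3), and the choroid plexus list the lowest (-0.42, and -0.83 without KO 3).

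Averaging the KO effect over the 3 regions asks for changes common to the brain. Lcn2, which encodes lipocalin 2, an acute-phase protein that binds iron carriers of bacteria, had the smallest p and the largest difference, 3.57 (adjusted p = 0.397 in limma over the 24 arrays). The standard error of that fit, 0.68, is too small for Lcn2. The fit used a correlation within animals of 0.00646 and Lcn2 had 0.966. Over animal means (n = 4 per genotype) the standard error was 1.37, and limma on animal means gave Lcn2 an adjusted p of 0.72. Its animal means were 11.80, 12.30 and 13.07 in KO 1, KO 2 and KO 3, 7.32 in KO 4, 8.91 in WT 1, and 6.83, 7.10 and 7.37 in WT 2, WT 3 and WT 4. Each animal had similar values in all 3 regions. Lyar (0.28), Zfp182 (0.30), Postn (0.42), Masp2 (0.34), Prss23 (0.58), Twf1 (0.32), Igfbp7 (0.39) and Dph3 (0.24) were higher and Smyd4 (-0.23) lower in all 4 KO animals than in all 4 WT animals. These genes were chosen for small p, which favours such separation. None passed: limma called 0 genes, and 1450 had an unadjusted p under 0.05 (809 higher, 641 lower; 979 by chance). With animal means limma called 0 genes (smallest adjusted p 0.356), with 1331 at unadjusted p under 0.05. KO 4 was left out after its low value had been seen, so the p that follows is no test of genotype. Lcn2 alone then passed in limma on animal means, with a difference of 4.83 (SE of animal means 0.63, n = 3 KO and 4 WT animals, adjusted p = 6.95e-04).

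**Figure D3:**
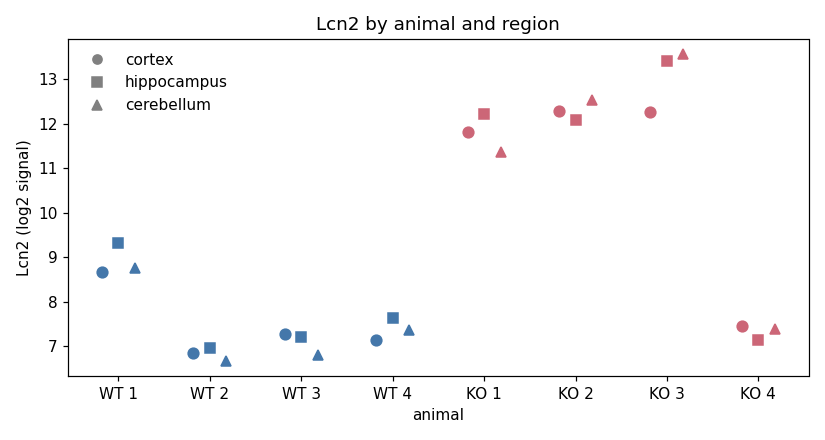
Lcn2 log2 signal of each array by animal, with a marker shape for each region, blue for WT and red for KO. KO 1, KO 2 and KO 3 lie between 11.37 and 13.56 in all regions, KO 4 between 7.13 and 7.44, and the WT animals between 6.67 and 9.33.

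The averaged effects of the genes named in advance were small: Cdkn1a 0.44 (SE 0.18, adjusted p = 0.661), Gadd45a -0.16, Gfap 0.15, Aqp4 -0.15, Slc1a2 0.02, Slc1a3 -0.05, Hmox1 0.01, Mt1 0.11, Mt2 0.12, Tspo -0.06, Fos -0.04, Arc -0.14, Per1 -0.12 and Dbp -0.03. None passed the threshold.

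Whether the KO effect differs between regions was tested directly. The genes of smallest p were Prodh, with effects of -0.18 in cortex, 0.35 in hippocampus and -0.18 in cerebellum, Cadm1, a synaptic adhesion gene (-0.49, 0.00 and 0.46), the olfactory receptor gene Olfr250 (-0.44, 0.29 and -0.05), Neurog1 (0.36, -0.13 and -0.34), Cep70 (-0.36, 0.00 and 0.19) and Ddah2 (0.26, 0.02 and -0.33). All 6 had an adjusted p of 0.921, limma called 0 genes, and 996 had an unadjusted p under 0.05 against 979 by chance. Set tests of the difference were chosen after the data were seen and took the arrays of an animal as independent. At the preset correlation 14 lists passed in at least 1 pair of regions (23 of 126 tests). With an estimated correlation 0 passed, the smallest adjusted p being 0.81.

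Genes within 10 Mb of the targeted locus were examined because DNA flanking a targeted allele can come from another strain. Of the 99 rows within that distance 0 passed in each comparison. At unadjusted p under 0.05 there were 11 in the cortex, 3 in the hippocampus, 11 in the cerebellum and 11 averaged. Over distances of 5, 10 and 20 Mb, the smallest p of Fisher's exact test was 0.133 (0.606 adjusted over 12 tests), for 12.2% of rows within 20 Mb against 9.46% elsewhere in the cerebellum.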

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

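All tests below except the splits of the samples were chosen after the result was seen; for the counts of striatal markers and of all neocortical markers the rule for reading them was written before the count was made, and the shares from 7 neocortical markers were added after that. Among 405 sets of 4 arrays (a named gene or a list mean in 1 group), 42 held 1 array far from the other 3, where chance gives about 20 (1 set in 20). KO 3 of the cerebellum accounted for 34 of the 42. Many of these genes were named because their list passed in the cerebellum, which rested largely on KO 3. Genes of a list also vary together, so neither count is a test of that array.

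In that array neuronal genes stood above the other 3 KO arrays: Uchl1 at 14.96, Nefl at 16.02, Nefh at 14.14, Nefm at 13.62 and the neuron marker mean at 14.99. Glial genes did so too: Gfap at 13.45, Hapln2 at 10.71, Ugt8a at 14.63, Mobp at 15.14, Nkx6-2 at 10.05, Sox10 at 11.38, Olig1 at 11.85, C1ql1 at 11.44 and Laptm5 at 11.01. List means were 13.82 for oligodendrocytes and myelin, 10.47 for their precursors, 12.97 for astrocytes and 9.54 for microglia. Metabolic and stress genes followed, with Msmo1 at 10.86, Nsdhl at 12.41, Gsta4 at 12.61, Prdx1 at 15.02, Fkbp5 at 12.38, Uqcrc1 at 12.37, and Cox6c at 16.37. The means were 11.75 for cholesterol synthesis and 12.01 for the antioxidant list. Choroid plexus genes were high against the other 3 KO arrays, with Ttr at 17.56, Kl at 11.21, Sostdc1 at 10.18 and a list mean of 10.70. That list mean lay within the range of the WT cerebellum arrays, 8.67 to 10.93. Cerebellar genes were low, with Fat2 at 11.76, Cbln3 at 14.14 and a list mean of 12.03. The remaining single arrays were WT 3 of the cerebellum for Ttr (9.65) and Hif3a (8.36), WT 2 of the cerebellum for Mt1 (16.66) and WT 3 of the hippocampus for Mef2c (13.87). In the cortex they were WT 1 for Lyar (9.47), WT 3 for Slc1a3 (12.11) and Tspo (8.31), and KO 1 for Arc (11.52).

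The cerebellar list shifts rest largely on KO 3, and carry-over of brainstem tissue, which adjoins the cerebellum, is a candidate explanation for that array. KO 3 was the highest of the 8 arrays for 14 of the 21 measured brainstem and spinal cord markers (chance 12.5% each; 3 of the 21 are also in a list fixed earlier), with Glra1 at 14.14 against at most 9.81, Tph2 at 10.35 against at most 6.25 and Slc6a5 at 12.42 against at most 10.46, but the excess was not confined to these, since it was also the highest for 9 of 16 thalamic and midbrain, 8 of 20 hippocampal and 7 of 15 striatal markers. Neocortical tissue met the rule written before, with 11 of 21 neocortical markers highest in KO 3, and of the 7 markers at least 4-fold higher in WT cortex Lamp5 was 12.22 (others at most 7.73), Rorb 11.68 (11.16) and Kcnh7 9.90 (9.28). It is argued against as the source (deposited values read as log2), since Lamp5 needs a share of neocortex of at least 23.6%, while Tbr1 (6.99, and 14.13 in WT cortex) allows at most 0.584% and Fezf2 at most 3.35%, and only 4 of the 7 allow a common share. A KO effect cannot be told apart for part of the pattern. Without KO 3, 5 of the 14 lists passed in the same direction at the preset correlation and the other 9 did not. With an estimated correlation none passed (adjusted p 0.986 each). Of genes at least 2-fold higher in cortex, 741 of 1025 were then higher in KO, against 54.3% of all genes. That shift decides nothing, since 7 of the 35 ways to split the 7 arrays gave a median as far from 0.

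In the KO cortex the rise of interneuron markers and the fall of excitatory ones may reflect olfactory bulb tissue in KO 1 and KO 4, since the bulb is rich in GABA neurons. These were the highest pair of the 8 arrays for 14 of 16 olfactory bulb markers (chance 3.57% each; 1 of the 16 is also in a list fixed earlier), with Th at 14.18 and 13.23 against at most 9.01, Cdhr1 at 12.52 and 11.83 against at most 7.67 and Eomes at 11.70 and 11.37 against at most 7.45. Striatal tissue, another source of GABA neurons, is argued against by 0 of 15 striatal markers with that pair highest. A KO effect in the other 2 animals cannot be told apart from none: the interneuron list had an adjusted p of 0.894 without the pair, from 2 KO arrays.

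Lcn2 was high in KO 1, KO 2 and KO 3 and not in KO 4, alike in all regions. Neutrophils, which carry Lcn2, cannot be told apart as a source: 0 of 13 neutrophil genes were higher in those 3 animals than in the other 5 (2 of the 13 are also in a list fixed earlier), but 10 of the 13 had means under 7.31, where signal over background is small. A swap of KO 4 with a WT animal stays open. Of the 4 possible exchanges 1, that with WT 1 at 8.91, would put all KO animals above all WT animals. KO 1, KO 2 and KO 3 already lay above all WT animals, so exchange with the highest WT animal had to do so. That count therefore decides nothing. A single wrong label of KO 4 stays open, as 3 of its 3 arrays lay within the WT range and the deletion cannot be read in brain, and so does an effect of the KO itself with variation between animals, for which the exact permutation of animal means gave a 2-sided p of 0.0857.

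The KO effect on several lists differed between regions at the preset correlation. With an estimated correlation 0 of 126 tests passed (smallest adjusted p 0.81). These set tests took the arrays of an animal as independent. Cerebellum minus hippocampus gave adjusted p of 1.72e-09 for the mitochondrial respiratory chain, 1.75e-05 for neuron markers, 1.77e-05 for microglia markers, 2.57e-04 for oligodendrocyte and myelin markers, 0.00194 for hypoxia and glycolysis, 0.00346 for heat shock proteins, 0.00572 for the antioxidant list and 0.0349 for choroid plexus markers. Cerebellum minus cortex gave 8.20e-05 for astrocyte markers, 2.81e-04 for granule and Purkinje markers, 5.48e-04 for cholesterol synthesis and 0.0382 for excitatory neuron markers. Hippocampus minus cortex gave 0.00913 for interneuron markers. Without cerebellum KO 3, 14 of the 126 tests passed, 10 of them among the 23. Of the differences printed here, those of oligodendrocyte and myelin markers (0.428), heat shock proteins (0.0555), the antioxidant list (0.414), granule and Purkinje markers (0.552) and cholesterol synthesis (0.217) did not pass without it. The other 8 did, with adjusted p of 0.0497 for microglia and for excitatory neuron markers. Without cortex KO 1 and KO 4, rich in olfactory bulb markers, the differences of interneuron (0.816) and excitatory neuron markers (0.938) did not pass. For 3 genes all KO values lay above all WT values in 1 region and below them in another. The effects differed by 0.53 for Prodh and 0.73 for Olfr250 (hippocampus over cortex, adjusted p = 0.921 by the F statistic over the 3 regions). For Eda2r they differed by 0.54 (cerebellum over hippocampus). Eda2r did not pass by that F statistic either, whose smallest adjusted p over all genes was 0.921.

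Each count was set against the 35 ways to split the same samples 4 against 4. The counts of genes past the threshold in the KO comparisons, 0 in each, are matched by 35 of 35 splits by construction, which decides nothing. Other splits gave up to 9 genes in the cortex, 18 in the hippocampus, 60 in the cerebellum, 7 averaged and 7 for the difference between regions. Of 34 other splits each, 2, 3, 3, 5 and 1 called any gene. A split that calls more genes than the real one may reflect structure among the samples or chance. These were not told apart, as data without structure were not used. For the other counts of the KO comparisons chance cannot be excluded. The counts at unadjusted p under 0.05 were matched by 11 splits in the cortex (1459, highest other 1999), 31 in the hippocampus (412, 1743), 6 in the cerebellum (1860, 2074), 4 averaged (1450, 2071) and 14 for the difference between regions (996, 1653). List counts were matched by 20 splits in the cortex (5, highest other 11), 34 in the hippocampus (2, 12) and 6 in the cerebellum (14, 17). The median of the other splits was 5 lists in the cortex, 5 in the hippocampus and 10 in the cerebellum. Lists thus often passed at the preset correlation in splits other than the real one, and its adjusted p cannot be taken at face value. Some of those splits keep 3 KO arrays together, so they are not free of a genotype difference. For the WT regions chance can be excluded: only the real split, 1 of 35, reached 267 genes between hippocampus and cortex (highest other 9), 1953 between cerebellum and cortex (11) or 1924 between cerebellum and hippocampus (1).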

How the results depend on the processing

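Leaving out KO animals (also from animal means), leaving out cortex KO 1 and KO 4 together and the number as a fixed block over all arrays were chosen after the data were seen. The WT region counts stayed within 1.5 times their values under every alternative run. For KO against WT the count of genes stayed at 0 in the hippocampus and for the difference between regions. The ordinary test with 1.5-fold gave 29 genes in the cortex and 23 in the cerebellum, and the number as a block within the cerebellum gave 35, all higher in KO, although WT and KO numbers are different animals; the cause was not tested. Leaving out 1 array gave 0 to 55 genes in the cortex (55 without KO 2, 34 without KO 3, where fewer arrays without olfactory bulb markers remain) and 0 to 1 averaged (1 without the KO 4 array of any region). Averaged, Lcn2 passed without KO animal 4, as 1 gene over all arrays and 1 over animal means, and 1 gene passed with the number as a fixed block, again Lcn2. The fits over all arrays give Lcn2 too small an error, KO 4 was left out for its low value and the numbers pair no animals. With animal means of all animals the count was 0.

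With an estimated correlation between genes the list counts were 0 in the cortex, 0 in the hippocampus and 0 in the cerebellum. They were also 0 in each region with fry, a self-contained test; the cause was not tested. In the hippocampus 1 list passed with its 8 arrays alone, 1 without dim rows and 1 with the number as a block; the cause was not tested. Leaving out 1 array gave 3 to 6 lists in the cortex, 0 to 4 in the hippocampus and 6 to 14 in the cerebellum (6 without KO 3). Without cortex KO 1 and KO 4, 2 lists passed in the cortex, and excitatory neuron markers turned to an upward direction with an adjusted p of 0.952. Of 1384 values of named genes in the KO comparisons with all arrays kept, 7 changed sign and 15 passed the threshold of their setting. For the ordinary test that threshold was unadjusted p under 0.05 and 1.5-fold. Settings that changed which rows were tested are not in this count. Of 4224 values with 1 array left out, 47 changed sign and 17 passed. Of 1147 values of named genes in the WT regions, 1135 kept direction and side of the threshold. Dim signal limits genes near the lower end of the scale, such as Postn, Dgat2l6 and Cenpk with means under 7.31, the 30th percentile of all rows.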

Other observations

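The tests in this part of animal differences, of numbers, of lists without cortex KO 1 and KO 4 and of the correlations between regions were chosen after the data were seen, and for the correlations the rule for reading them was written before they were computed. The lists of reactive astrocyte genes, of cytokines and inflammation and of the interferon response did not pass in any region. Microglia markers passed in the cerebellum at the preset correlation (adjusted p = 4.94e-06, and 0.0763 without KO 3). Reactive astrocyte genes, a list that includes Lcn2, had 17 of 24 members higher in the KO cerebellum (median 0.07, adjusted p = 0.197), 13 in the cortex (0.03, 0.721) and 10 in the hippocampus (median -0.02 but mean 0.16, 0.874). Cytokine and inflammation genes gave adjusted p of 0.606 in the cerebellum, 0.88 in the cortex and 0.709 in the hippocampus. Interferon response genes were higher in 17 of 24 members in the hippocampus (median 0.08, adjusted p = 0.178), 15 in the cortex (0.721) and 11 in the cerebellum (0.869).

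Several genes differed between animals of a genotype alike in all 3 regions. An F statistic in limma for animals within genotype, over the 24 arrays, called 12 genes: Lcn2 (adjusted p = 1.16e-09), Nfkbia (1.78e-05), Mid1 (4.30e-05), Eps8l1 (0.00122), Sgk1 (0.00439), Txnip (0.00726), 1700048O20Rik (0.0209), Gh (0.0369), Gabra2 (0.0369), Ccn1 (0.039), Hspa1a (0.039) and BC051142 (0.0445). Of 100 arrangements of the numbers within groups, only the real one, 1 of 100, gave as many, and the highest other gave 2, so chance can be excluded. Mid1, an X-linked ubiquitin ligase gene, was 13.63, 13.39 and 12.51 in cortex, hippocampus and cerebellum of KO 3 and 10.99, 11.21 and 10.80 in KO 2. Gabra2, a GABA receptor subunit gene, was 12.22, 13.70 and 10.86 in WT 4, below the other 7 animals in each region. The chaperone gene Hspa1a was highest in KO 4 in each region, at 10.84, 10.76 and 11.02.

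Gh and Prl, hormone genes of the pituitary, were high in WT 3, Prl in cortex and hippocampus alone. Gh was 17.46 in cortex (other animals 7.78 to 10.25), 14.49 in hippocampus (8.09 to 11.09) and 10.86 in cerebellum (7.98 to 9.13). The highest of the others in cortex and hippocampus was WT 1. Prl was 13.20 in cortex and 10.26 in hippocampus, where the other animals lay between 6.88 and 8.08. In the cerebellum Prl was 7.54 in WT 3, within the range of the others (7.06 to 7.57). Pomc, another pituitary gene, lay between 6.81 and 7.85 in the 24 arrays. Ttr ranged from 10.14 to 15.28 in the cortex and from 10.65 to 18.33 in the hippocampus, across both genotypes.

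Nfkbia and Sgk1, genes induced by stress hormones and cytokines, were also called by an F statistic in limma for the animal number, alike in WT and KO (adjusted p = 2.81e-06 and 0.00217). That fit took the 3 regions of an animal as independent. Both genes differed between animals alike in all 3 regions, so these p are too small. Nfkbia was 8.91, 9.35, 10.04 and 10.59 in the cortex of WT 1, WT 2, WT 3 and WT 4 and 9.28, 9.08, 9.63 and 10.21 in that of KO 1, KO 2, KO 3 and KO 4. Of the 24 ways to pair KO numbers with WT numbers, 5 gave at least the 2 genes called here (highest other 7), so chance cannot be excluded. Residuals of WT and KO arrays with the same number correlated from -0.243 to 0.297 across genes, and in 1 of 12 cases the same number was the best match, so the numbers do not pair the animals by this measure.

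Across genes, the KO effects of the regions were nearly unrelated: the correlation was 0.0702 between cortex and hippocampus, 0.113 between cortex and cerebellum and 0.0216 between hippocampus and cerebellum. Genes are not independent replicates, and 7, 12 and 17 of the 35 splits gave values as large (highest others 0.19, 0.251 and 0.34), so chance cannot be excluded for any of the 3.

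Without KO 1 and KO 4 of the cortex, striatal markers were higher in KO in 15 of 15 members (median 0.26, adjusted p = 0.0116 at the preset correlation) and oligodendrocyte and myelin markers in 17 of 18 (median 0.23, adjusted p = 0.0319), from 2 KO arrays against 4. With an estimated correlation both lists had an adjusted p of 0.977. The striatal mean was 10.97 and 10.64 in KO 2 and KO 3 and 9.81, 10.69, 10.88 and 10.50 in WT 1, WT 2, WT 3 and WT 4.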
